A study of Mus musculus with 30 samples.

How the data were processed

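RNA was measured in tibialis anterior muscle of male and female mice, uninjured or 4, 7, 11 or 15 days after volumetric muscle loss, with 3 libraries in each of 10 groups, per the labels. Total RNA was used, and a commercial laboratory extracted the RNA and made the libraries, per the labels' protocols. Reads were aligned with STAR to mm39, per the submitters' processing notes, which also name edgeR, and the file headers name an aligned file made from 2 input read files. No versions are given. The counting program, the gene annotation and the handling of strand and of reads shared between genes are not given in the sources used here. The deposited files hold 1 count per gene symbol and library for 26264 symbols, and no columns of normalized values were used. In the counts from 1 to 20 of each library 65.5 to 77.5% were even, and 765 to 984 genes had a count of 2 against 218 to 350 with a count of 1, as would be seen if both reads of a pair were counted. Mitochondrially encoded genes were not analysed here. All values below were computed from the deposited counts.

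Genes were kept by edgeR's filterByExpr with the 10 groups, which left 17136 genes and removed 9128. Library sizes were scaled with TMM factors. Counts were fitted with edgeR 4.0.16 (glmQLFit, 1 mean per group, all 30 libraries in 1 fit), and contrasts were tested with glmQLFTest in R 4.3.3. P-values were adjusted over the tested genes by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. SE values were computed from the same fits. The contrasts were injured against uninjured muscle at each day with both sexes weighted equally, successive days and day 15 against day 4, females against males in uninjured muscle, the sex difference in the injury response at each day and jointly over the 4 days, and injured against uninjured muscle within each sex. Log2 CPM for levels and principal components used a prior count of 2. Total counts were 13089999 to 57277336 per library. The lowest ratio of chi-square to degrees of freedom between replicates was 16.2, so the spread between replicates was far above that of counting alone.

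Fold changes against a group with no counts are given as lower bounds, computed against a floor of 6 counts over the group, which is 3 read pairs. Where the uninjured libraries of 1 sex held 6 counts or fewer, levels are given in place of a fold against uninjured muscle, since the fitted fold depends on the prior count. For genes with few counts in uninjured muscle the ratio is given with a 95% counting interval, which leaves out the spread between libraries. List medians are also given with such genes at their bounds where this changes them.

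Before the data were examined, 43 gene lists with 643 symbols were fixed for cell types, signalling and metabolism, and the tests, the alternatives and the rule for named genes were written down. Lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over 172 list and day tests; between-day and sex contrasts were adjusted separately. Camera with a correlation estimated from the data was run as an alternative, as was fry. Of the 172 tests camera called 101, 84 up and 17 down. Named genes were chosen by rule. For each day against uninjured muscle these were the 5 called genes with the largest rise and the 5 with the largest fall, with mean CPM of at least 5 and no overlap between the 6 injured and the 6 uninjured libraries. Each list gave the 3 called members with the largest change at the day with most called members, at a mean CPM of at least 1. Each contrast between days gave 3 genes per direction at a mean CPM of at least 5, the female to male contrast 5 per direction at a mean CPM of at least 1, and each sex difference in response the 3 smallest p-values per direction. A further 28 genes were always reported, and predicted genes without a symbol of their own were passed over. Some genes that the rule names are not reported here.

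Replicate numbers were checked for pairing by correlating each library's residuals. Pairs with the same number had a mean r of 0.0125 (135 pairs) and pairs with different numbers -0.00633 (270 pairs), and 12 of 30 libraries were closest to their own number, so no replicate block entered the tests. No library was left out of the tests. The library labelled female day 11 replicate 3 carries Y-linked transcripts and almost no Xist and was kept under its label.

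The alternatives were RLE scaling, library size alone, no low-count filter, a filter of CPM above 1 in 3 libraries, DESeq2 1.42.0, an added 2-fold threshold, a fit with only the compared groups, a replicate block, and leaving out each library in turn. After the data were seen, 3 more were added: leaving out the library whose sex genes disagree with its label, thinning every library to the smallest total, and halving the counts. The tests were tried on simulated data with known changes, drawn from the means and sizes of the real libraries. The compared groups were given equal means, and 66 or 67 genes with a mean CPM of at least 5 were then changed at each fold. The shares called therefore do not cover genes of lower CPM. The share of false calls does not carry over to a real contrast in which most genes were called. For day 4 against uninjured muscle (16734 genes) 19.4, 73.1 and 100% of genes changed by 1.5-, 2- and 4-fold were called, and 2.29% of calls were false. For day 15 against day 11 (16944 genes) these were 10.4, 70.1, 98.5 and 6.30%. For females against males in uninjured muscle (16926 genes) they were 10.4, 29.9, 86.4 and 5.62%, and for the sex difference at day 15 (16932 genes) 0, 1.49, 71.2 and 4%.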

Results

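RNA was sequenced from the tibialis anterior, the muscle at the front of the lower leg, of male and female mice. The muscles were uninjured or had been taken 4, 7, 11 or 15 days after volumetric muscle loss, an injury in which a piece of muscle tissue is removed. Each of the 10 groups of sex and time held 3 libraries, 30 in all. The question was how gene expression in injured muscle differed from that in uninjured muscle at each day, and the design also allowed comparisons between days and between the sexes. The labels do not say that the libraries came from separate animals, or that uninjured and injured muscle did, so the p-values measure the spread between these samples. Total counts per library ranged over 13089999 to 57277336. They were 40757683 to 48860849 in uninjured muscle, 47936072 to 57277336 at day 4, 20674040 to 52483561 at day 7, 27129433 to 38555740 at day 11 and 13089999 to 30024528 at day 15. Of 26264 genes listed, 17136 had enough counts to be tested.

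Transcripts of sex-linked genes were examined first, since they check the labels. Xist, the RNA that silences an X chromosome in female cells, lay between 83.0 and 1062 CPM (counts scaled by library size and TMM factor) in 14 libraries labelled female and reached at most 3.49 CPM in the 15 labelled male. The library labelled female day 11 replicate 3 held Xist at 0.109 CPM, and the Y-linked Ddx3y at 57.4 CPM, within the 30.6 to 94.1 CPM of the libraries labelled male. It was kept under its label. Directions at day 11 for Y-linked genes rest on it, as does their fall from day 11 to day 15.

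**Figure D1:**
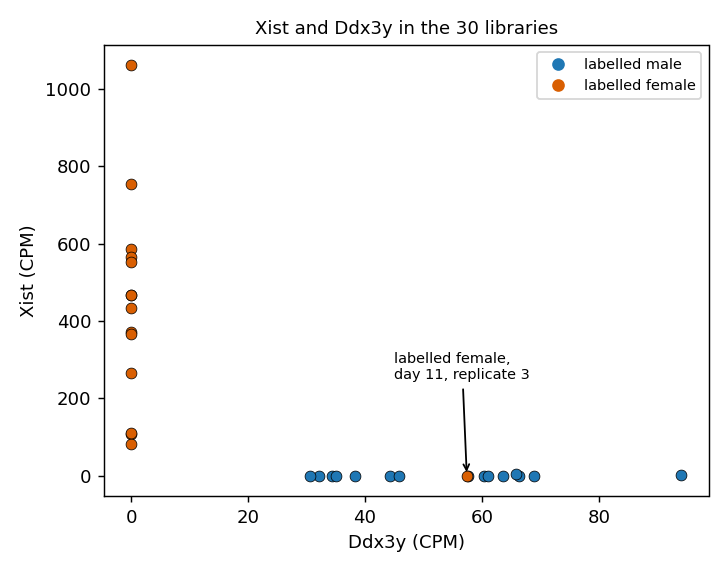
Xist (vertical axis, CPM) against Ddx3y (horizontal axis, CPM) in the 30 libraries, one point per library, coloured by the sex in its label. The library labelled female day 11 replicate 3, at 0.109 CPM of Xist and 57.4 CPM of Ddx3y, lies among the libraries labelled male.

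Uninjured and injured muscle were separated along the first principal component of log2 CPM, which held 57.5% of the variance, and the second held 14.4%. In uninjured muscle the 10 most abundant genes took 25.7 to 32.3% of the counts, against 5.56 to 19.2% in injured muscle. The mean TMM factor was accordingly 0.527 in uninjured muscle and 1.30, 1.19, 1.16 and 1.08 at days 4, 7, 11 and 15. With these factors the median gene had a log2 fold change against uninjured muscle of 0.17, 0.24, 0.32 and 0.26 at the respective days, and with library size alone 1.47, 1.42, 1.46 and 1.30. Fold changes are therefore relative to that scaling. They are given on the log2 scale ± SE, and CPM values as mean ± SD with n = 6 unless a sex is named.

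**Figure D2:**
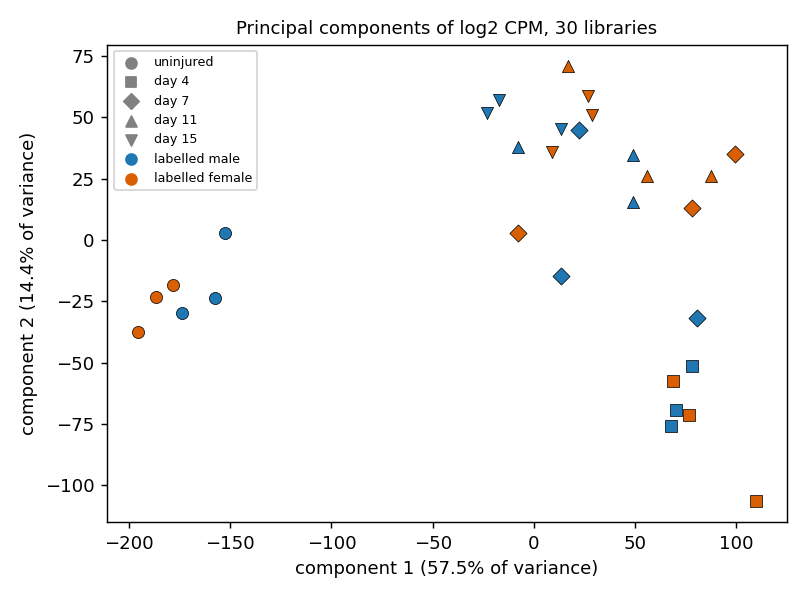
First (horizontal) and second (vertical) principal components of log2 CPM, one point per library, with symbols for the time point and colours for the labelled sex. The first component, 57.5% of the variance, parts the 6 uninjured libraries from the 24 injured ones.

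At day 4, genes of inflammatory cells were far above uninjured muscle. All 16 macrophage markers rose, with a median of 5.74. Adgre1, which encodes the macrophage surface protein F4/80, went from 1.11 ± 0.639 to 74.0 ± 25.3 CPM (6.23 ± 0.52), Ms4a7 rose by 10.04 ± 0.74, the lysosomal gene Cd68 by 7.41 ± 0.59 and the chemokine receptor Cx3cr1 by 6.39 ± 0.45. Of the repair and lipid-associated macrophage markers 14 of 15 rose and 1 fell (median 4.77). Among them, Spp1, which encodes osteopontin, reached 1805 ± 596 CPM from 1.34 ± 0.804 (10.48 ± 0.81), and Trem2, a lipid-sensing receptor, rose by 9.32 ± 0.61. The proton pump subunit Atp6v0d2 had 6 counts over all uninjured libraries, and its ratio was 567-fold (194 to 2751), the interval covering counting error only. The arginine-degrading enzyme Arg1 rose to 36.7 ± 38.7 CPM from 0.0892 ± 0.0796 (22.7 without female day 4 replicate 2) and the mannose receptor Mrc1 by 3.51 ± 0.29.

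Monocyte and neutrophil genes rose alongside. 13 of 14 inflammatory monocyte markers rose (median 5.33), including the Fc receptor Fcgr1 (77.3 ± 12.3 CPM from 0.262 ± 0.449), the integrin Itgam (6.55 ± 0.50) and Chil3 (21.1 ± 7.08 CPM from 0.129 ± 0.148), whose reads may be shared with its close paralog. 10 of 11 neutrophil markers rose (median 3.93, or 3.19 with genes near the floor at their bounds). They included Clec4d (7.13 ± 0.70), Csf3r, the receptor for granulocyte colony-stimulating factor (5.64 ± 0.39), and the collagenase Mmp8 (3.11 ± 1.67 CPM from 0.0927 ± 0.115); the calcium-binding S100a8 rose by 4.78 ± 0.65. 9 of 12 dendritic cell markers rose and 1 fell (median 3.15), with Itgax at 7.68 ± 0.57, Flt3 at 3.88 ± 0.858 CPM from 0.114 ± 0.128 and Ccr7 at 3.27 ± 1.14 CPM from 0.146 ± 0.201. Of 29 inflammatory cytokines and chemokines 26 rose and 1 fell (median 5.14, or 4.71 at bounds). The monocyte attractant Ccl2 rose by 7.45 ± 0.62, Ccl8 rose to 36.3 ± 12.1 CPM from 0.0815 ± 0.0896, Ccl3 to 8.38 ± 1.48 CPM from 0.115 ± 0.158 and the interleukin Il1b to 3.66 ± 1.97 CPM from 0.145 ± 0.215. Cxcl5 had no counts in uninjured muscle and was at least 87.4-fold higher, and the interleukin Il6 stood at 18.8-fold (6.32 to 92.2) its uninjured level. Tlr13, an innate sensor of bacterial RNA, rose to 58.7 ± 12.8 CPM from 0.0957 ± 0.130, with no counts in uninjured females, as for Ccl3. Camera with a preset correlation called these 6 lists, at adjusted p of 4.50e-07 to 0.00875; with an estimated correlation the adjusted p was 0.367 and none was called. Adjusted over the list alone, the number of called members was the same except for inflammatory monocyte markers (14) and dendritic cell markers (11).

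Antigen presentation, complement and interferon response genes were also higher at day 4. All 10 MHC class II presentation genes rose (median 3.79), among them the protease Ctss (8.25 ± 0.66), the costimulator Cd86 (4.49 ± 0.44) and H2-DMb1 (4.17 ± 0.37). So did 13 of 15 complement genes (median 2.67) and all 19 interferon-stimulated genes (median 2.02), with Mx1 at 5.71 ± 0.66, Zbp1 at 5.67 ± 0.53 and Oas1a, which may share reads with its paralogs, at 4.12 ± 0.41. In the haemostasis and fibrinolysis list 14 of 20 rose and 2 fell (median 2.20). All 11 NK and cytotoxic markers rose (median 4.64, or 4.55 at bounds), with Klrk1 at 4.05 ± 1.45 CPM from 0.0919, Il2rb at 3.14 ± 1.06 CPM from 0.0734 ± 0.0685 and Ccl5, also a chemokine of other leukocytes, at 4.64 ± 0.79. Camera called these 5 lists at adjusted p of 3.83e-05 to 0.00159, and none with an estimated correlation (adjusted p of 0.367 to 0.389). The number of called members, adjusted over the list alone, was the same in each of these lists. T cell markers were mixed, 9 higher and 2 lower of 15 (median 2.59, or 1.76 at bounds), without a camera call (adjusted p = 0.168). Cd3e, a subunit of the T cell receptor complex, did not pass the test (0.352 ± 0.166 CPM from 0.161 ± 0.125, adjusted p = 0.0834 by edgeR). B and plasma cell markers went both ways, with 3 of 11 higher and 3 lower; Cd22 rose by 4.90 ± 0.48, Cd79b by 2.14 ± 0.32, and Mzb1 changed by -1.12 ± 0.33, a direction that reversed with library size alone (0.16).

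Extracellular matrix genes rose together. All 18 collagens were higher at day 4 (median 3.80); Col1a1 went from 78.0 ± 46.7 to 3815 ± 827 CPM (5.76 ± 0.51), Col1a2 rose by 4.99 ± 0.46, Col3a1 by 4.58 ± 0.43 and Col12a1 by 5.26 ± 0.63. 19 of 22 matrix glycoproteins and crosslinking enzymes rose (median 3.41), among them fibronectin, Fn1 (4.85 ± 0.49), and periostin, Postn (7.59 ± 0.64). 16 of 18 matrix proteases and inhibitors rose and 1 fell (median 3.88), with the macrophage elastase Mmp12 at 43.0 ± 18.5 CPM from 0.0933 ± 0.106, the inhibitor Timp1 at 8.02 ± 0.59 and Adam12 at 7.26 ± 0.61. 13 of 14 activated fibroblast and myofibroblast markers rose (median 4.89), and the smooth muscle actin Acta2 rose by 2.58 ± 0.37. In the TGF-beta signalling list 16 of 20 rose and 3 fell (median 1.56), with the ligand Tgfb1 at 3.22 ± 0.22, the latent TGF-beta binding protein Ltbp2 at 54.2 ± 17.9 CPM from 0.155 ± 0.210 and thrombospondin, Thbs1, at 4.64 ± 0.59. Camera called these 5 lists at adjusted p of 1.37e-06 to 0.00472, and none with an estimated correlation (adjusted p of 0.367). Called members, adjusted over the list alone, were as many in each of these lists. Fibro-adipogenic progenitor markers were higher in 11 and lower in 4 of 16 (camera adjusted p = 0.0952); Pdgfra, a receptor of these progenitors, rose by 2.36 ± 0.20, Cd248 by 3.46 ± 0.34 and Mfap5 by 2.86 ± 0.35, and Has1, a hyaluronan synthase, had a ratio of 34.1-fold (11.7 to 354).

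Genes of proliferation and of new muscle fibres were high at day 4. 19 of 20 cell cycle genes rose (median 5.73); the proliferation marker Mki67 went from 0.768 ± 0.669 to 120.2 ± 29.3 CPM (7.76 ± 0.45), and Ccnb1, Cenpf and Bub1, with 6 counts each over the uninjured libraries, stood at 629-fold (215 to 3050.2), 496-fold (169.6 to 2406) and 333-fold (114 to 1618). 12 of 15 genes of myogenic differentiation and fusion rose and 2 fell (median 1.98). The membrane fusion gene Mymk went from 0.126 ± 0.133 to 379 ± 42.1 CPM; its partner Mymx had no counts in uninjured muscle and was at least 1846-fold higher. The myogenic regulators Myog and Myod1 rose by 5.73 ± 0.40 and 1.98 ± 0.25. 13 of 15 developmental and regenerating fibre genes rose (median 3.49), with embryonic myosin, Myh3, at 1945 ± 321 CPM against 4.29 ± 2.89 (8.87 ± 0.64), and perinatal myosin, Myh8, at 5.28 ± 0.47. 10 of 14 satellite cell markers rose and 1 fell (median 1.56); Pax7, the transcription factor of these muscle stem cells, rose by 2.68 ± 0.33, Megf10 by 4.78 ± 0.33, Fgfr4 by 3.54 ± 0.23 and Vcam1 by 3.31 ± 0.31. Camera called these 4 lists at adjusted p of 9.16e-09 to 0.0102, and none with an estimated correlation (adjusted p = 0.367). Adjusted over the list alone, the number of called members was the same in each of these lists. R3hdml, with 2 counts in uninjured muscle, was at 2353-fold (422 to 92944), and Stra6l, with none, was at least 367-fold higher.

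Transcripts of mature muscle fibres fell. All 22 fast contractile genes were lower at day 4 (median -3.43). The fast myosin Myh4 went from 85625 ± 14386 to 4866 ± 2824 CPM (-4.14 ± 0.52), the calcium buffer Pvalb changed by -4.45 ± 0.64 and the myosin-binding protein Mybpc2 by -4.41 ± 0.65. Ckm, the muscle creatine kinase, changed by -4.06 ± 0.55. All 18 genes of glycolysis and glycogen breakdown fell (median -3.09), among them the glycogen phosphorylase Pygm (-3.87 ± 0.45), Gpd1 (-3.93 ± 0.48) and Phkg1 (-3.66 ± 0.53). All 24 genes of oxidative phosphorylation and the TCA cycle fell (median -2.51), with the cytochrome oxidase subunits Cox7a1, Cox6a2 and Cox8b at -3.50 ± 0.43, -3.38 ± 0.43 and -3.28 ± 0.39. 15 of 17 fatty acid oxidation genes fell (median -1.92), with Acadm at -2.65 ± 0.36, Acadvl at -2.53 ± 0.30 and Eci1 at -2.51 ± 0.28. Camera called these 4 lists at adjusted p of 9.16e-09 to 7.70e-05, and none with an estimated correlation (adjusted p of 0.367 to 0.386). The number of called members, adjusted over the list alone, was the same in each of these lists. The library labelled female day 4 replicate 2 stood below the other 5 in all 4 lists, as for fast contractile genes (mean log2 CPM of 8.85 against 10.87 to 11.50), and in Ckm (8.33 against 10.62 to 11.33). The 5 genes chosen for the steepest falls were Smox, a polyamine oxidase (-4.54 ± 0.29), Klhl33 (-4.47 ± 0.54), the potassium channel Kcng4 (-4.66 ± 0.84), Timp4 (-4.67 ± 0.62) and Ces1d, which may share reads with its gene family (-4.84 ± 0.82).

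Several other gene groups were mixed, or took a direction that depended on the scaling. Slow fibre genes were higher in 7 and lower in 3 of 14 (median 0.90, camera adjusted p = 0.114); the slow troponins Tnni1 and Tnnc1, also made in developing muscle, rose by 6.69 ± 0.69 and 5.61 ± 0.60, and sarcolipin, Sln, by 5.32 ± 0.52. Muscle atrophy genes were higher in 6 and lower in 8 of 17. The metallothionein Mt2 rose by 4.38 ± 0.45, while myostatin, Mstn, changed by -3.76 ± 0.46 and the glucocorticoid-responsive Klf15 by -3.38 ± 0.47; the list median of -0.35 turned positive with library size alone. 12 of 16 endothelial markers fell (median -0.79, camera adjusted p = 0.00273, or 0.430 with an estimated correlation), again a direction that flipped with library size alone. The endothelial junction gene Pecam1 was -0.28 ± 0.15, adjusted p = 0.0915 by edgeR. Pericyte and smooth muscle markers were higher in 4 and lower in 7 of 13 (median -0.94, positive with library size alone). Smooth muscle myosin, Myh11, changed by -2.20 ± 0.25, Synpo2 by -1.962 ± 0.54, and Mustn1 rose by 1.94 ± 0.38.

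In all, edgeR's quasi-likelihood test called 12526 of 17136 genes at day 4, 6864 higher and 5662 lower. With library size alone as the scaling the split was 12603 higher and 1482 lower, so the share of falling genes depended on the TMM factors. Each called list of falling muscle genes named above kept its direction under that scaling.

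**Figure D3:**
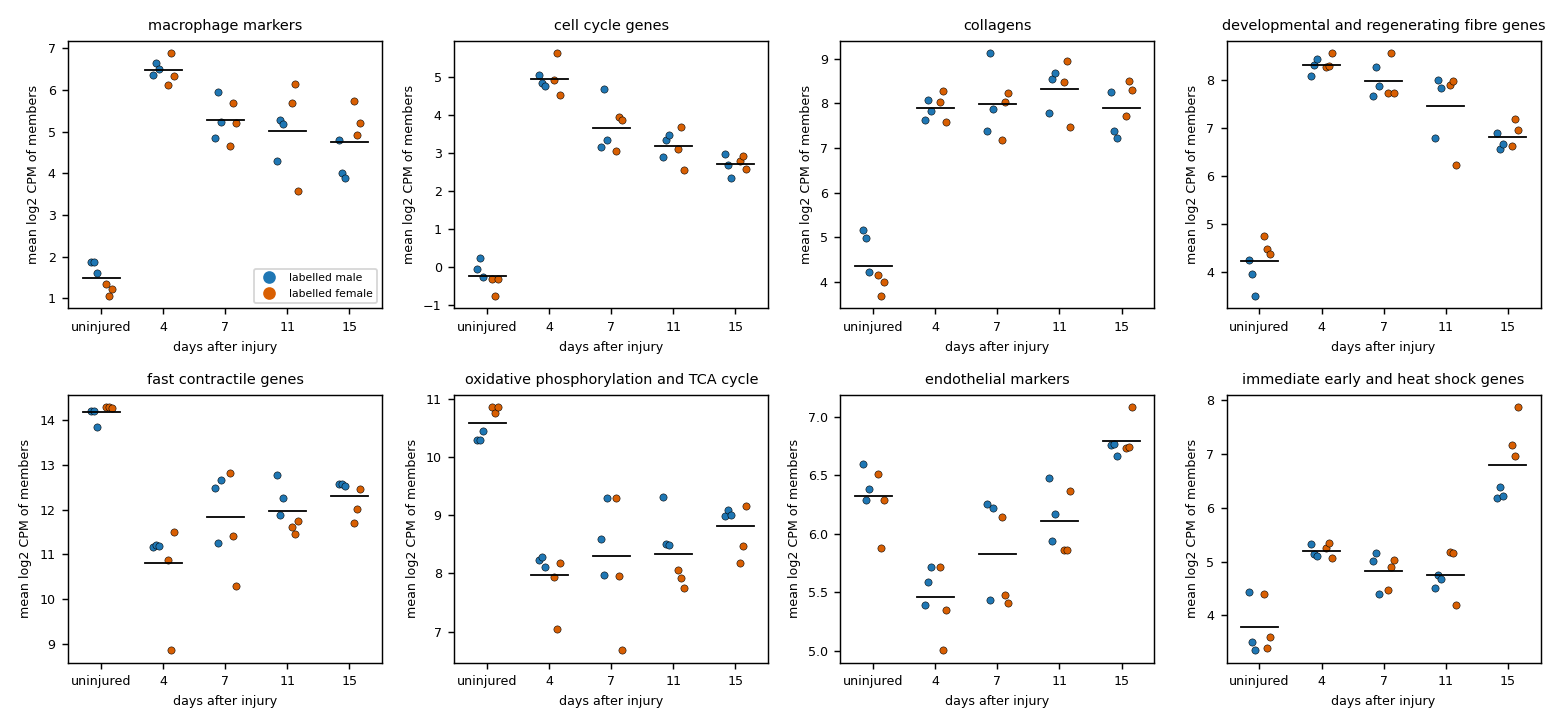
Mean log2 CPM of the members of 8 gene lists (vertical axes) in uninjured muscle and 4, 7, 11 and 15 days after injury (horizontal axes). Points are single libraries coloured by labelled sex and black lines are the mean of 6 libraries; macrophage, cell cycle, collagen and developmental fibre genes lie above uninjured muscle at day 4, and fast contractile and oxidative phosphorylation genes below it.

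At day 7 the inflammatory groups were still above uninjured muscle. 13 of 16 macrophage markers (median 4.54), 13 of 14 inflammatory monocyte markers (median 4.01) and 10 of 10 MHC class II genes (median 3.48) were higher. Adgre1 stood at 23.8 ± 8.67 CPM, Itgam at 4.595 ± 0.46, Mrc1 at 2.32 ± 0.28, Arg1 at 3.74 ± 4.45 CPM from 0.0892 ± 0.0796 (1.98 without male day 7 replicate 2), Ccl2 at 4.90 ± 0.59, Il1b at 2.51 ± 1.30 CPM from 0.145 ± 0.215 and S100a8 at 5.04 ± 0.65. T cell markers rose in 11 of 15 (median 3.07, or 1.95 at bounds), Cd3e included (0.570 ± 0.260 CPM from 0.161 ± 0.125). All 18 collagens rose (median 4.07), with Col1a1 at 5.87 ± 0.52, Col3a1 at 4.90 ± 0.44, Fn1 at 4.61 ± 0.48, Postn at 8.39 ± 0.66, Acta2 at 2.19 ± 0.37, Pdgfra at 1.86 ± 0.20 and Tgfb1 at 2.22 ± 0.21. The prolyl hydroxylase P4ha3 had 6 and Podnl1 2 counts in uninjured muscle, with ratios of 822-fold (281 to 3987) and 919-fold (165 to 36347). 8 of 11 cartilage and bone genes rose and 1 fell. The osteoblast regulators Runx2 and Sp7 were at 4.37 ± 0.37 and 1.06 ± 0.557 CPM from 0.0844 ± 0.131 (no counts in uninjured females), and aggrecan, Acan, at 483-fold (86.6 to 19122); the list was not called (camera adjusted p = 0.0506).

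New fibre genes also remained above uninjured muscle at day 7. Myog was at 5.15 ± 0.39, Myod1 at 0.82 ± 0.25, Myh3 at 8.02 ± 0.62, Myh8 at 5.91 ± 0.49, Mymk at 142 ± 78.0 CPM from 0.126 ± 0.133, Pax7 at 1.03 ± 0.32 and Mki67 at 7.06 ± 0.44. 13 of 15 developmental fibre genes (median 3.82) and 17 of 20 cell cycle genes (median 4.21) rose. All 22 fast contractile genes (median -2.28) and all 24 of oxidative phosphorylation and the TCA cycle (median -2.00) fell, with Myh4 at -2.79 ± 0.49 and Ckm at -3.33 ± 0.53. Camera called these lists and those of the macrophage, inflammatory monocyte, MHC class II, T cell and collagen genes at day 7 at adjusted p of 9.16e-09 to 0.0441, and none with an estimated correlation (adjusted p of 0.367 to 0.430). Called members, adjusted over the list alone, were as many except for developmental and regenerating fibre genes (14). The steepest falls were in Amd1, the S-adenosylmethionine decarboxylase, whose reads may be shared with a near-identical copy (-4.54 ± 0.44), Smox (-4.16 ± 0.29), Tspan8 (-3.99 ± 0.62), Phospho1 (-3.82 ± 0.50) and Ces1d (-3.49 ± 0.77). In all, 12259 genes were called, 7127 higher and 5132 lower, against 12665 and 1212 with library size alone. The T cell list was no longer called without male uninjured replicate 3, female uninjured replicate 2 or male day 7 replicate 3, nor with library size alone.

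At day 11, lymphocyte, matrix and connective tissue genes were high. 14 of 15 T cell markers rose (median 3.67, or 3.10 at bounds), with Cd4, which macrophages can also carry, at 6.47 ± 0.66, the kinase Lck at 4.74 ± 0.51, Cd28 at 1.32 ± 0.32 and Cd3e at 1.11 ± 1.01 CPM from 0.161 ± 0.125 (0.712 without female day 11 replicate 2, which stood apart for the T cell list). 10 of 11 tenocyte markers rose (median 2.31), among them tenomodulin, Tnmd (4.59 ± 0.53), Kera (4.17 ± 0.64) and Comp (3.84 ± 0.61). 9 of 11 cartilage and bone genes rose (median 3.44, or 3.01 at bounds), and 13 of 16 fibro-adipogenic progenitor markers rose with 2 lower (median 1.76). All 18 collagens (median 4.05) and 21 of 22 matrix glycoproteins and crosslinking enzymes (median 3.33) rose. Col1a1 stood at 5091 ± 2945 CPM (6.18 ± 0.52), Col3a1 at 5.55 ± 0.45, Fn1 at 4.81 ± 0.49, Postn at 8.33 ± 0.66, tenascin, Tnc, at 6.65 ± 0.76 and Pdgfra at 1.84 ± 0.20. The ratios of P4ha3, Acan and Podnl1 were 783-fold (268 to 3799), 1336-fold (239 to 52788) and 615-fold (110.1 to 24319).

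Macrophage markers rose in 14 of 16 at day 11 (median 4.26), with Adgre1 at 4.90 ± 0.49, Itgam at 4.49 ± 0.46, Mrc1 at 2.54 ± 0.28 and Ccl2 at 3.90 ± 0.59. 13 of 15 developmental fibre genes rose and 2 fell (median 3.55): the embryonic acetylcholine receptor subunit Chrng was at 7.46 ± 0.40, Myh3 at 6.93 ± 0.59, Myh8 at 5.47 ± 0.48 and Dlk1 at 5.66 ± 0.54. Myog was at 4.52 ± 0.37, Mymk at 95.3 ± 53.5 CPM from 0.126 ± 0.133 and Mki67 at 6.28 ± 0.43, and 17 of 20 cell cycle genes rose (median 3.47). Pax7 (0.25 ± 0.32, adjusted p = 0.496 by edgeR) and Myod1 (0.46 ± 0.24, adjusted p = 0.0929 by edgeR) did not pass the test. 21 of 22 fast contractile genes (median -2.37) and all 24 of oxidative phosphorylation and the TCA cycle (median -2.14) fell, with Myh4 at -3.12 ± 0.50 and Ckm at -4.05 ± 0.55. Steep falls were also seen in Tspan8 (-5.44 ± 0.67), Phospho1 (-5.30 ± 0.55), Sdr39u1 (-4.42 ± 0.44), Ces1d (-5.30 ± 0.85) and Amd1 (-4.82 ± 0.45). Camera called the 11 lists given for day 11 at adjusted p of 1.09e-08 to 0.0223, and none with an estimated correlation (adjusted p of 0.367 to 0.433). Adjusted over the list alone, the number of called members was the same in each of these lists. In all, 12406 genes were called, 7319 higher and 5087 lower, against 12652 and 1385 with library size alone. The Y-linked Eif2s3y, which may share reads with its X-linked relative, Ddx3y and Uty were called higher (66.9 ± 57.2 CPM from 47.3 ± 53.8; 37.9 ± 30.1 CPM from 37.8 ± 42.6; and 12.6 ± 11.4 CPM from 8.87 ± 9.74), with no counts in uninjured females. Without female day 11 replicate 3 the log2 values were -0.10, -0.23 and -0.10.

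At day 15, immediate early genes, which respond within minutes to growth factors or stress, stood above every other time. 11 of 12 members of the immediate early and heat shock list rose against uninjured muscle (median 2.46). Fos went from 5.27 ± 3.26 CPM in uninjured muscle to 475 ± 380.1 CPM (6.29 ± 0.49), Fosb was at 8.08 ± 0.58 and Egr1 at 3.95 ± 0.54 (5.26 without female uninjured replicate 1). 11 of 16 endothelial markers rose and 3 fell (median 0.66, camera adjusted p = 0.141), with Robo4 at 1.38 ± 0.22, Cldn5 at 1.22 ± 0.22, Pecam1 at 0.54 ± 0.15 and the water channel Aqp1 at -1.21 ± 0.43. 10 of 14 adipocyte markers rose and 1 fell (median 2.05, camera adjusted p = 0.260): adiponectin, Adipoq, was at 3.80 ± 0.94, the lipid droplet gene Cidec at 3.98 ± 1.04 and Cfd at 2.47 ± 0.84, with 5 of 6 libraries in that direction for Cfd. Neuromuscular junction and denervation genes rose in 11 and fell in 3 of 18 (camera adjusted p = 0.106), with Chrng at 6.34 ± 0.39, Runx1 at 4.94 ± 0.34 and Chrnd at 3.02 ± 0.33. Krt8, a keratin of simple epithelia, rose to 68.4 ± 33.4 CPM from 0.0873 ± 0.0770.

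Inflammatory and matrix genes remained above uninjured muscle at day 15. 15 of 16 macrophage markers (median 3.61) and 14 of 15 complement genes (median 2.40) rose, with C3ar1 at 4.49 ± 0.50, C5ar1 at 4.23 ± 0.50, C4b at 4.09 ± 0.32, Adgre1 at 4.26 ± 0.48, Il1b at 5.601 ± 7.07 CPM from 0.145 ± 0.215 (2.74 without female day 15 replicate 3) and Ccl2 at 4.48 ± 0.59. 17 of 20 haemostasis and fibrinolysis genes rose and 2 fell (median 1.89), with Tfpi2 at 4.09 ± 0.53, coagulation factor gene F10 at 1.31 ± 0.705 CPM from 0.106 ± 0.141 and Thbs1 at 3.91 ± 0.57. All 14 activated fibroblast and myofibroblast markers (median 4.79) and all 18 collagens (median 3.53) rose, with Postn at 7.18 ± 0.63, Lrrc15 at 7.15 ± 0.79, Col1a1 at 5.25 ± 0.50 and Col3a1 at 5.20 ± 0.45. P4ha3, Acan and Igfbp2 had ratios of 367-fold (125 to 1781), 386-fold (68.9 to 15296) and 144-fold (49.1 to 703). Myog was at 3.65 ± 0.36, Myh3 at 5.10 ± 0.55 and Mki67 at 5.71 ± 0.42, 12 of 15 developmental fibre genes rose with 2 lower, and 17 of 20 cell cycle genes rose with 1 lower. Pax7 (-0.59 ± 0.34, adjusted p = 0.127 by edgeR), Myod1 (0.02 ± 0.25, adjusted p = 0.944 by edgeR) and Cd3e (0.169 ± 0.148 CPM from 0.161 ± 0.125, adjusted p = 0.786 by edgeR) did not pass the test. 19 of 22 fast contractile genes (median -1.84) and 23 of 24 of oxidative phosphorylation and the TCA cycle (median -1.68) were lower, with Myh4 at -2.47 ± 0.48, Ckm at -3.44 ± 0.53 and Lrrc20 at -4.00 ± 0.52.

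Camera called the immediate early, myofibroblast, complement, haemostasis, collagen, macrophage, cell cycle, developmental fibre, fast contractile and oxidative phosphorylation lists at day 15 at adjusted p of 5.20e-08 to 0.00250, and none with an estimated correlation (adjusted p of 0.367 to 0.389). The number of called members, adjusted over the list alone, was the same except for cell cycle genes (20). In all, 11823 genes were called, 6809 higher and 5014 lower, against 11956 and 1360 with library size alone. Arg1 (0.492 ± 0.235 CPM from 0.0892 ± 0.0796) lost its day 15 call without male uninjured replicate 1 or female uninjured replicate 3. Xist was called higher only at day 15 (2.21 ± 0.86), with females at 266 to 552 CPM from 83.0 to 111. Females already stood at 366 to 435 CPM at day 4 and 587 to 1062 at day 7. The call was lost without male uninjured replicates 1 or 2 or male day 15 replicate 3 (1.15 without the last).

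**Figure D4:**
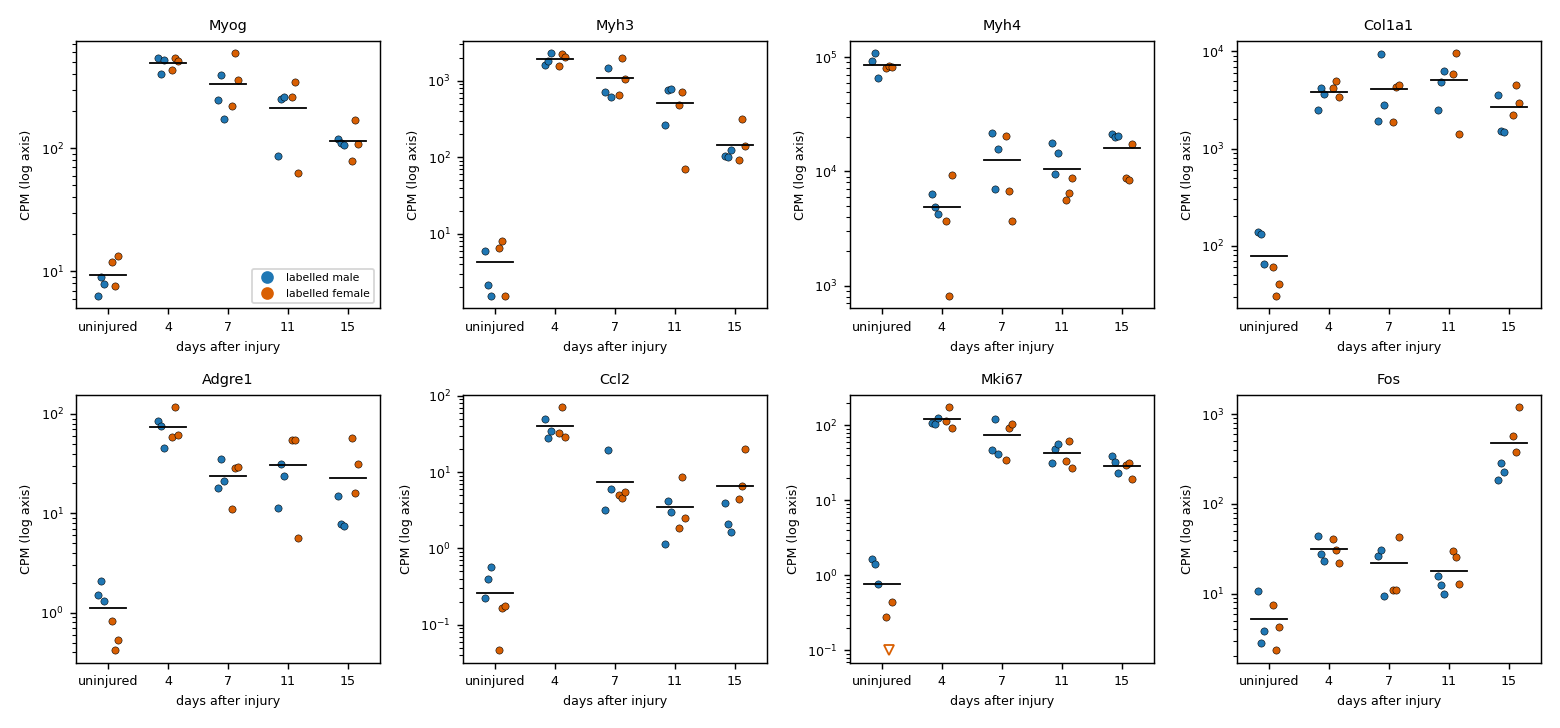
CPM (vertical log axes) of 8 named genes in uninjured muscle and 4, 7, 11 and 15 days after injury (horizontal axes), with points for libraries coloured by labelled sex and black lines for the mean of 6 libraries; the open triangle marks a library without Mki67 counts, placed below the scale of the others. Myog and Myh3 are highest at day 4, Myh4 is lower at all injured days, and Fos is highest at day 15.

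From day 4 to day 7, inflammatory and proliferation genes fell and contractile genes rose. 12 of 16 macrophage markers fell (median -1.11), as did 10 of 14 inflammatory monocyte markers (median -1.45), 11 of 29 cytokines and chemokines (median -0.91), 18 of 20 cell cycle genes (median -1.11) and 6 of 15 genes of myogenic differentiation and fusion (median -0.60). 14 of 22 fast contractile genes rose (median 1.13). Without female day 4 replicate 2 the change in mean log2 CPM of fast contractile genes was 0.64, against 1.03 with it. Called members of these 6 lists, adjusted over the list alone, were 15, 11, 12, 19, 7 and 14. Camera called these 6 lists, among 3 higher and 9 lower in all, and none with an estimated correlation (adjusted p of 0.487 to 0.700). Large falls were in Arg1 (-3.39 ± 0.54) and the chemokine receptor Ccr1 (-3.26 ± 0.46), and the largest rises in Adamts16 (3.08 ± 0.37), the noncoding RNA Meg3 (2.94 ± 0.39) and Spon2 (2.72 ± 0.52). edgeR called 6034 genes, 3174 higher and 2860 lower, against 2019 and 3438 with library size alone, and 3974 without male day 7 replicate 1.

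Between day 7 and day 11, edgeR called 10 genes, 7 higher and 3 lower. Tropomodulin, Tmod2, rose by 1.10 ± 0.18, the progenitor surface protein Cd34 by 0.82 ± 0.15, Atf5 by 0.74 ± 0.15, Tgfbr3 by 0.63 ± 0.12, Th by 3.71 ± 0.54, Aldh3a1 by 2.98 ± 0.56 and Gm12185 by 1.73 ± 0.26. Iqsec3 changed by -1.38 ± 0.23, Fgfr4 by -1.19 ± 0.21 and Ptprn by -1.89 ± 0.37. Tgfbr3, Th, Aldh3a1, Gm12185 and Ptprn lie outside the naming rule and were listed after their values were seen. Fibro-adipogenic progenitor markers had a median of 0.60 and tenocyte markers of 1.43, with 1 and 0 members called, or 9 of 16 and 8 of 11 adjusted over the list alone. Both lists were called by camera and neither with an estimated correlation (adjusted p of 0.169 to 0.346). Camera called 10 lists higher and 6 lower, none of the 16 with an estimated correlation. Among them were T cell markers (median 0.93), cell cycle genes (-0.62), developmental fibre genes (-0.43), repair macrophage markers (-0.42) and satellite cell markers (-0.31), with 0, 0, 0, 0 and 1 members called, or 5, 5, 1, 0 and 4 adjusted over the list alone. The change in mean log2 CPM of cell cycle genes was -0.29 without male day 7 replicate 2, against -0.49 with it. For developmental and regenerating fibre genes it was -0.27 without female day 11 replicate 3, against -0.51. Repair and lipid-associated macrophage markers gave -0.28 without that library and -0.35 without male day 11 replicate 1, against -0.53. The gene count was 3 without male day 7 replicate 2 or female day 11 replicate 1. It was 4 without male day 11 replicate 1 or female day 7 replicates 2 or 3. It was 6 without male day 11 replicates 2 or 3. Without female day 7 replicate 1 it was 29, and 31 without female day 11 replicate 3. With library size alone it was 5, all higher, and with DESeq2 112. Tmod2 passed the test whichever library was left out, and calls were lost for Cd34 without male day 7 replicates 1 or 2, male day 11 replicates 1 or 3, female day 7 replicates 2 or 3 or female day 11 replicates 1 or 2, for Atf5 without male day 7 replicates 2 or 3, male day 11 replicates 1, 2 or 3, female day 7 replicates 2 or 3 or female day 11 replicate 1, for Iqsec3 without male day 7 replicate 2, female day 11 replicate 1 or female day 7 replicate 3 and for Fgfr4 without male day 7 replicate 2, male day 11 replicates 1 or 2, female day 7 replicates 2 or 3 or female day 11 replicate 1.

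From day 11 to day 15, immediate early genes rose. 9 of 12 members of that list rose (median 1.85), Fosb by 5.50 ± 0.50, Fos by 4.59 ± 0.45, Egr1 by 2.78 ± 0.51 and Junb by 2.46 ± 0.26; the heat shock genes Hspa1a and Hspa1b, near-identical copies of each other, rose by 1.64 ± 0.25 and 1.43 ± 0.30. This list was called with an estimated correlation too (camera, adjusted p = 0.0493). 7 of 16 endothelial markers rose (median 0.64) and 3 of 14 adipocyte markers rose (median 1.44), while 10 of 19 interferon-stimulated genes (median -1.03), 7 of 15 T cell markers (median -1.53) and 5 of 15 developmental fibre genes (median -0.62) fell. Adjusted over the list alone, the called members of these 5 lists were 13, 9, 15, 10 and 6, and of the immediate early list 9. The library labelled female day 11 replicate 2 stood apart for the interferon-stimulated genes (log2 CPM of 6.29 against 3.78 to 4.42 in the other 5) and T cell markers (1.86 against -0.32 to 0.46). Without it the change in mean log2 CPM of the former was -0.52, against -0.88 with it. Camera called these 5 lists, among 12 higher and 7 lower in all, and none of the 5 with an estimated correlation (adjusted p of 0.249 to 0.618). Depp1 rose by 3.26 ± 0.47 and the collagenase Mmp13 changed by -3.68 ± 0.97. Eif2s3y and Uty were called lower (49.0 ± 53.9 CPM from 66.9 ± 57.2, and 8.62 ± 9.63 from 12.6 ± 11.4), but on the log2 scale stood at 0.11 and 0.07 without the library labelled female day 11 replicate 3. For Mmp13, day 15 vs day 11, the value was -5.81 without female day 15 replicate 2. Calls were also lost for Eif2s3y without male day 11 replicates 2 or 3, female day 11 replicate 3 or any day 15 library. Uty lost its call without any male day 11 library, any day 15 library or female day 11 replicate 3. Mmp13 lost its call without male day 11 replicate 2, female day 11 replicates 1 or 2 or any male day 15 library. So it did without female day 15 replicates 1 or 3. edgeR called 727 genes, 342 higher and 385 lower. Without male day 11 replicates 2 or 3 the count was 371 or 305. Without male day 15 replicates 2 or 3 it was 313 or 353. Without female day 11 replicates 2 or 3 it was 301 or 1506. It was 308 without female day 15 replicate 3. The balance depended on the analysis. It was 357 and 347 with RLE scaling, 194 and 297 with library size alone, 368 and 337 with a replicate block, 277 and 135 with only the compared groups, 526 and 714 by DESeq2, and 575 and 931 without female day 11 replicate 3.

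Between day 4 and day 15, 13 of 16 macrophage markers (median -2.02), 19 of 20 cell cycle genes (median -2.37) and 11 of 15 genes of myogenic differentiation and fusion (median -1.54) fell. 15 of 16 endothelial markers (median 1.33) and 17 of 22 fast contractile genes (median 1.36) rose. In these 5 lists the called members, adjusted over the list alone, were 15, 19, 12, 15 and 18. Camera called these 5 lists, among 10 higher and 10 lower in all, and none of the 5 with an estimated correlation (adjusted p of 0.447 to 0.643). Spp1 changed by -6.38 ± 0.68, to 22.2 ± 9.91 CPM, Arg1 by -5.99 ± 0.65 and R3hdml by -4.87 ± 0.56, while Fosb rose by 5.17 ± 0.49, the macrophage-secreted Retnla by 4.70 ± 0.54 and Spon2 by 4.54 ± 0.55. edgeR called 8934 genes, 4302 higher and 4632 lower, against 2773 and 6238 with library size alone.

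In uninjured muscle, females differed from males in sex-linked and slow fibre genes. Xist was at 101 ± 15.6 CPM in females and 0.257 ± 0.317 in males (n = 3 each, 8.55 ± 1.49). The Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y had no counts in females and were at least 871-, 202-, 153- and 1089.6-fold lower there. 4 of 14 slow fibre genes were higher in females (9 called adjusted over the list alone, median 2.51), including slow myosin, Myh7 (4.96 ± 1.14), and the troponin Tnnc1 (3.50 ± 0.80). Camera called the list at adjusted p = 2.54e-09, and not with an estimated correlation (adjusted p = 0.160). The spread within females was wide: Myh7 stood at 26.7 ± 42.5 CPM against 0.859 ± 0.604 in males, and the muscle stretch sensor Csrp3 at 272 ± 192 against 16.6 ± 12.02 (4.03 ± 0.87). The small heat shock gene Hspb7 was higher in females (2.91 ± 0.68), and Bco2, a carotenoid-cleaving enzyme, had no counts in females and 40 over the 3 male libraries, at least 6.196-fold lower. Of 18 collagens 2 were lower in females (4 called adjusted over the list alone, median -0.94, camera adjusted p = 8.63e-06, or 0.752 with an estimated correlation). edgeR called 110 genes, 31 higher and 79 lower in females, against 15 and 93 with library size alone, 37 and 63 with RLE scaling and 165 and 170 by DESeq2. The count was 39 and 57 without male uninjured replicates 2 and 3 in turn. It was 41, 57 and 32 without female uninjured replicates 1, 2 and 3. It was 168, 55 higher and 113 lower, without female day 11 replicate 3, which is not among the 6 compared. Without female uninjured replicate 2, Myh7 was at 1.37 and Tnnc1 at 2.18. Xist and Bco2 passed the test without any 1 of the 6 uninjured libraries. With 1 library left out, calls ended for Myh7 and Tnnc1 without any male uninjured library or female uninjured replicate 2. That of Hspb7 ended without any male library or female replicates 1 or 3. Csrp3 lost its call without male replicates 1 or 2 or female replicates 1 or 3. Those of Eif2s3y and Ddx3y ended without male replicates 2 or 3 or any female library. Those of Uty and Kdm5d ended without any 1 of the 6. Uninjured males held 231 to 3175 counts of these 4 Y-linked genes and females 0, so the lost calls mark no overlap of the sexes. The fitted spread includes female day 11 replicate 3, with its Y-linked transcripts. With every library thinned to the smallest total the calls of Bco2 (adjusted p = 0.143) and of Eif2s3y, Ddx3y, Uty, Kdm5d, Myh7, Tnnc1 and Hspb7 (0.0515 to 0.0958) ended, and with counts halved that of Kdm5d (0.0608).

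Few genes were called for a sex difference in the response to injury. Cdk19, a kinase of the transcriptional mediator complex, had an interaction, female response minus male response, of 1.84 ± 0.29, 1.77 ± 0.29, 1.77 ± 0.29 and 1.91 ± 0.29 at days 4, 7, 11 and 15 (edgeR adjusted p = 0.00964, 0.0125, 0.00777 and 0.00364). It stood at 55.8 ± 23.2 CPM in uninjured males and 17.4 ± 1.42 in uninjured females, against 23.8 ± 1.53 and 28.0 ± 3.88 at day 15 (n = 3 each). The carbonyl reductase Cbr2 was called at days 4, 11 and 15 (2.30 ± 0.42, 2.78 ± 0.42 and 3.10 ± 0.42), and was at 77.2 ± 18.5 CPM in uninjured males and 13.95 ± 1.86 in uninjured females. Bco2, without counts in uninjured females, was called at all 4 days. Selenbp1 had a negative interaction at day 4 (-1.88 ± 0.35), as did Osbp2, Cacna2d2 and Hectd2os at day 7 (-2.93 ± 0.51, -2.55 ± 0.52 and -2.41 ± 0.50) and Cacna2d2, Fkbp5 and Mybph at day 15 (-2.86 ± 0.54, -2.42 ± 0.49 and -2.27 ± 0.49); Gramd1c had a positive one at day 7 (3.00 ± 0.52). Bco2 at days 7, 11 and 15, and Cdk19 and Cbr2 at days 11 and 15, passed the test whichever 1 library was left out. The day 4 calls of Cdk19 and Bco2 were lost without female uninjured replicates 1 or 3. So they were without male day 4 replicate 1 or female day 4 replicate 2. Cbr2 lost its call without male uninjured replicates 1 or 2, female day 4 replicate 2 or any female uninjured or male day 4 library. Selenbp1 lost it without any 1 of the 12 libraries. At day 7 Cdk19 and Gramd1c lost their calls without female uninjured replicate 1 or female day 7 replicate 3. Gramd1c also lost it without male day 7 replicate 3. Osbp2 lost it without female uninjured replicate 1 or female day 7 replicates 2 or 3. Cacna2d2 and Hectd2os lost theirs without any 1 uninjured library, male day 7 replicate 3 or female day 7 replicates 2 or 3. Cacna2d2 also lost it without male day 7 replicate 1. At day 15 Cacna2d2, Fkbp5 and Mybph lost their calls without male day 15 replicate 3 or female day 15 replicates 1 or 3. Fkbp5 and Mybph also lost them without any 1 female uninjured library, male uninjured replicate 1 or male day 15 replicate 2. Cacna2d2 lost it without male or female uninjured replicate 3 and Fkbp5 without male uninjured replicate 2. Mybph lost it without male uninjured replicate 3 or male day 15 replicate 1. With every library thinned, Bco2 lost its calls at all 4 days (edgeR adjusted p = 0.432, 0.253 and 0.184 at days 4, 7 and 11, and 0.1 at day 15). So did Cdk19, Cbr2 and Selenbp1 at day 4, Gramd1c, Osbp2, Cacna2d2 and Hectd2os at day 7, and Cacna2d2, Fkbp5 and Mybph at day 15 (0.0515 to 0.425). Halved counts ended the calls of Bco2 (0.0766), Cbr2 and Selenbp1 at day 4, Cacna2d2 and Hectd2os at day 7 and Mybph at day 15.

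edgeR called 8 interaction genes at day 4 (7 positive, 1 negative), 21 at day 7 (18 and 3), 10 at day 11 (10 and 0) and 36 at day 15 (33 and 3), and a joint test over the 4 days called 6. With library size alone day 4 gave 5 positive and 0 negative. The day 15 test called 1.49% of simulated 2-fold and 71.2% of 4-fold differences (16932 genes tested). DESeq2 called 208 genes there, and the fit of only the compared groups 278, so how many genes differ is left open. Leaving out single libraries moved these counts. At day 4 the count was 4 without male uninjured replicates 2 or 3 or female day 4 replicate 1. It was 0 without female uninjured replicates 1 or 3, male day 4 replicate 1 or female day 4 replicate 2. It was 5 without female uninjured replicate 2 and 3 without male day 4 replicates 2 or 3. At day 7 it was 12 without male uninjured replicate 1, 13 without male uninjured replicate 2 or male day 7 replicate 1, 2 without female uninjured replicate 1 or female day 7 replicate 3, 9 without female uninjured replicate 3, 6 without male day 7 replicate 3, 204 without female day 7 replicate 1 and 5 without female day 7 replicate 2. At day 11 it was 18 without male uninjured replicate 1 and 5 without female uninjured replicate 1 or male day 11 replicate 2. It was 6 without male day 11 replicates 1 or 3 and 22 without female day 11 replicate 1. At day 15 it was 16 without male uninjured replicate 2, 22 without female uninjured replicate 1, 14 without female uninjured replicate 3, 11 without male day 15 replicate 2 or female day 15 replicate 3, 8 without male day 15 replicate 3 and 15 without female day 15 replicate 1. The joint count was 3 without male uninjured replicate 2 and 0 without any 1 female uninjured library. It was 10 without male day 15 replicate 1 and 13 without female day 7 replicate 1. With all libraries edgeR gave 1312 of 17136 genes at an unadjusted p under 0.05 at day 4 and 1062 jointly. Chance alone would give a share of 0.05, so many may be false. DESeq2 called 37 and 93. Of the 43 lists, slow fibre genes had a median interaction of -2.23 at day 4 with 0 of 14 members called, or 6 adjusted over the list alone (camera adjusted p = 2.34e-07, or 0.220 with an estimated correlation).

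Within each sex, the tests against the 3 uninjured libraries of that sex called 9858, 8804, 8755 and 8167 genes in males and 11096, 11020, 11235 and 10493 in females at days 4, 7, 11 and 15. In males 5273, 5049, 5008 and 4522 of these were higher and 4585, 3755, 3747 and 3645 lower, against 10821, 10351, 10188 and 9390 higher and 958, 630, 828 and 872 lower with library size alone. In females 6185, 6464, 6692 and 6059 were higher and 4911, 4556, 4543 and 4434 lower, against 11994, 12120, 12182 and 11208 higher and 1221, 967, 1157 and 969 lower. At day 11 the females include replicate 3, with its Y-linked transcripts. Without it 6021 genes were higher and 4843 lower there, and 11 interactions positive and 0 negative. The difference in response was tested by the interactions above, which called 8 to 36 genes a day. Myh4 at day 4 changed by -4.11 in males and -4.17 in females, Col1a1 by 4.94 and 6.58, and Adgre1 by 5.39 and 7.07. The edgeR test of the difference between the sexes gave adjusted p = 1.000, 0.654 and 0.685 for these 3 genes.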

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

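The 3 tests of the sex difference given at the end of this part were chosen only after the result was seen. A level far from those of the other 5 libraries of its time point, by a gap test, was found in 25 of 340 levels of lists and genes tested, where 1 in 20, or 17, would be met by chance. Values are log2 CPM, with the range of the other 5 in parentheses. Female day 4 replicate 2 stood apart for 7 of them: dendritic cell markers 2.33 (2.86 to 2.99), fast contractile genes 8.85 (10.87 to 11.50), oxidative phosphorylation and TCA cycle 7.05 (7.95 to 8.29), glycolysis and glycogen breakdown 7.47 (8.70 to 9.14), fatty acid oxidation 4.78 (5.53 to 5.85), Ckm 8.33 (10.62 to 11.33) and Pdgfra 6.08 (5.42 to 5.63). The others were, in male uninjured replicate 3, fast contractile genes 13.84 (14.20 to 14.29); in male uninjured replicate 1, Schwann cell markers 3.13 (1.52 to 2.00); in male day 4 replicate 3, interferon-stimulated genes 5.64 (4.3998 to 4.82); in male day 7 replicate 2, haemostasis and fibrinolysis 3.94 (2.69 to 2.97) and Ccl2 4.31 (1.71 to 2.61); in female day 4 replicate 1, Il1b 2.93 (1.28 to 1.81); in male day 7 replicate 1, Cd3e -2.41 (-0.88 to -0.11); in male day 4 replicate 1, Acta2 8.70 (9.37 to 9.62). At the later days they were, in female day 11 replicate 2, interferon-stimulated genes 6.29 (3.78 to 4.42) and T cell markers 1.86 (-0.32 to 0.46); in female day 11 replicate 3, adipocyte markers 3.47 (1.74 to 2.21); in female day 15 replicate 3, neutrophil markers 1.65 (-1.24 to -0.19), endothelial markers 7.08 (6.66 to 6.77), satellite cell markers 3.96 (3.68 to 3.77) and Il1b 4.32 (0.82 to 1.959); in female day 15 replicate 1, erythroid genes -1.47 (-0.55 to -0.13); in female day 15 replicate 2, Myh3 8.32 (6.53 to 7.13); in male day 11 replicate 3, Il6 -3.23 (-1.76 to -1.33).

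The tested difference between the sexes in the response to injury also drew attention. The edgeR test called 8 genes at day 4, 21 at day 7, 10 at day 11, 36 at day 15 and 6 jointly. Among named genes, female minus male responses at day 4 were 1.84 for Cdk19, 7.74 for Bco2, 2.30 for Cbr2 and -1.88 for Selenbp1. At day 7 they were 8.07 for Bco2, 1.77 for Cdk19, 3.00 for Gramd1c, -2.93 for Osbp2, -2.55 for Cacna2d2 and -2.41 for Hectd2os. At day 11 they were 8.74 for Bco2, 2.78 for Cbr2 and 1.77 for Cdk19. At day 15 they were 3.10 for Cbr2, 8.40 for Bco2, 1.91 for Cdk19, -2.86 for Cacna2d2, -2.42 for Fkbp5 and -2.27 for Mybph. The Bco2 values are no bounds, since uninjured females had no counts and the fitted value depends on the prior count.

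Other splits of the same libraries were counted for each of these results, 25 splits each, with the sex labels reassigned within each time point used. As many genes as the real split gave were called by 4 splits at day 4 (real 8, highest other 14), 4 at day 7 (21 and 267), 2 at day 11 (10 and 40) and 6 for the joint test (6 and 1746), the real split included, so chance is not excluded for these. At day 15 only the real split, 1 of 25 and so the smallest share possible, reached 36, the highest other being 14. No other of these results did so, and chance is not excluded for day 15 either. The splits also reassign sex among the uninjured libraries, so they cannot separate a sex difference before injury from a difference in response. The real day 15 count was no higher than 14 without female uninjured replicate 3 (14), male day 15 replicate 2 (11), male day 15 replicate 3 (8) or female day 15 replicate 3 (11). The splits calling 267 and 1746 genes point to a structure of the samples, which was not identified.

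The called sex differences may start from the uninjured libraries: in 68 of 75 gene and day calls, 50 genes in all, the female to male difference was larger in uninjured than in injured muscle. Of the 50 genes 34 were also called between the sexes in uninjured muscle. With 1 uninjured library left out the 4 counts summed to 62, 40 and 66 without male uninjured replicates 1, 2 and 3, and to 29, 65 and 30 without female uninjured replicates 1, 2 and 3, so the part of a single library cannot be told apart. Thinning every library to the smallest total left a sum of 22, and the higher totals of the uninjured libraries cannot be told apart either, since thinning also lowers power. A difference between male and female mice before injury is the biological explanation in the design; whether it lies in the mice or in these 6 uninjured libraries stays open.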

How the results depend on the processing

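Values without the library labelled female day 11 replicate 3, with libraries thinned to the smallest total and with counts halved were chosen only after the results were seen. The counts for injured against uninjured muscle at each day, with both sexes or within one, stayed within 1.5 times under every alternative run. Scaling set their split between higher and lower genes, as given in the report. Direction was kept for the named gene values compared (317, called or not, and 313 with DESeq2) under RLE scaling, both filters, the 2-fold threshold, DESeq2, thinning and halving (5 calls lost at 2-fold, 1 with RLE scaling, 4 without a low-count filter, 25 when thinned, 9 when halved). With library size alone 12 were lost and 5 reversed. The cause was not tested unless stated.

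The sex difference at day 4 gave 5 genes with RLE scaling, 5 with library size alone and 4 with no low-count filter. Library size alone gave 5 for day 11 against day 7 and 23 for the day 11 sex difference, for which a filter of CPM above 1 in 3 libraries gave 16. The 2-fold threshold, by its construction, left 2425 genes for day 7 against day 4, 419 for day 15 against day 11 and 4865 for day 15 against day 4. Without female day 11 replicate 3 the counts were 31 for day 11 against day 7 and 1506 for day 15 against day 11. Females against males then gave 168. Thinned to the smallest depth, females against males gave 38 genes, and the sex differences at days 4, 7 and 15 and jointly 0, 3, 11 and 1; the edgeR count of 0 stands beside 1312 genes at an unadjusted p under 0.05 with all counts and 37 by DESeq2. With counts halved these 4 sex differences gave 1, 9, 22 and 3. DESeq2 gave 112 for day 11 against day 7, 1240 for day 15 against day 11, 335 for females against males, and 37, 58, 82, 208 and 93 for the sex differences at days 4, 7, 11 and 15 and jointly. With only the compared groups in the edgeR fit, which leaves fewer libraries to estimate the spread, these were 1, 412, 254, and 1, 0, 2 and 278 for the 4 days. The day 7 count of 0 stands beside 58 by DESeq2 and 1704 genes at an unadjusted p under 0.05 in the full fit. Many of the 1704 and 1312 may be chance. The joint test had no 2-fold or compared-groups value. Of the 172 list tests against uninjured muscle, camera with an estimated correlation called 0, against 101 with the preset one and 148 by fry.

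With library size alone Mzb1 and Krt10 at day 4 reversed to 0.16 and 0.26, and Pecam1 at days 4, 7 and 11 to 1.03, 0.81 and 1.10. Without female day 11 replicate 3, Eif2s3y, Ddx3y and Uty at day 11 reversed to -0.10, -0.23 and -0.10. For day 15 against day 11 Eif2s3y and Uty reversed to 0.11 and 0.067. These fitted values depend on the prior count, since uninjured and day 15 females had no counts of these genes. Their ranges with 1 library left out were -0.10 to 7.18, -0.23 to 6.38 and -0.10 to 5.99 at day 11, -7.16 to 0.11 for Eif2s3y, day 15 vs day 11, and -6.01 to 0.07 for Uty, day 15 vs day 11. Leaving out 1 of the compared libraries at a time gave 3974 to 6777 genes for day 7 against day 4, 3 to 31 for day 11 against day 7, 301 to 1506 for day 15 against day 11 and 32 to 82 for females against males. On the same terms the sex differences ranged over 0 to 6, 2 to 204, 5 to 22 and 8 to 46 at days 4, 7, 11 and 15, and 0 to 13 jointly. A count of 0 at day 4 came from edgeR without female uninjured replicates 1 or 3, male day 4 replicate 1 or female day 4 replicate 2, and jointly without any 1 female uninjured library; the report gives the unadjusted and DESeq2 counts beside them.

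With a replicate block the counts against uninjured muscle were 12486, 12270, 12376 and 11801 at the 4 days, those between days 5975, 9, 705 and 8869, females against males 91, and the sex differences 6, 18, 10 and 28, with 5 jointly. It ended 8 named gene calls, at adjusted p of 0.0514 to 0.0776 by edgeR: Myh7, Hspb7 and Kdm5d for females against males, Cacna2d2 and Hectd2os for the sex difference at day 7, Mybph for that at day 15, and Eif2s3y and Uty for day 15 against day 11. Lower depth, by thinning, ended 25 named gene calls and 2 list calls. Of the 25 the report names 22 for the sexes. The others were Hdc at day 7, Il6 at day 11 and Arg1 at day 15. Halving ended those of Arg1 at day 15 and Uty for day 15 against day 11 besides those in the report.

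On the linear scale, leaving out 1 library moved 69 of 299 called named gene values by over 1.5 times, 50 of them only away from 0. Of those not given in the report, the smaller log2 values were, at day 7, Il6 2.84 and Postn 7.79 without male day 7 replicate 2. At day 11 Sfrp2 was 7.34 without female day 11 replicate 2. At day 15 Il6 was 4.98 and S100a8 3.24 without female day 15 replicate 3, and Acan 8.22 without female day 15 replicate 2. Others were Spon2 for day 7 against day 4, 2.00 without female day 7 replicate 3, and Mmp13 for day 15 against day 11, -2.83 without male day 11 replicate 2. Csrp3 for females against males was 3.36 without female uninjured replicate 1. Called list medians that became smaller were T cell markers, 2.47 without male day 7 replicate 3 at day 7. At day 11 they were 3.04 without male uninjured replicate 3 and 2.86 without female day 11 replicate 2. Without the latter NK and cytotoxic markers were at 4.53 and inflammatory monocyte markers at 3.83.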

Other observations

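The tests of the library labelled female day 11 replicate 3 and of the immediate early genes were chosen only after the data were seen, that of depth before its own result. Several gene groups not described above changed in part; none of their lists was called by camera against uninjured muscle. Between days camera called Schwann cell (day 11 against 7, day 15 against 4), mast cell (day 11 against 7, day 15 against 11 and 4), angiogenic and erythroid (day 15 against 11) and keratinocyte lists (days 7 and 15 against 4), all higher (adjusted p of 3.21e-05 to 0.0415), and none with an estimated correlation (0.169 to 0.553). Of 15 Schwann cell markers, days 4, 7, 11 and 15 had 2 higher and 8 lower; 2 higher and 4 lower; 7 higher and 1 lower; 7 higher and 1 lower (medians -0.77, -0.26, 0.77 and 0.88, the first 2 positive with library size alone; camera adjusted p of 0.197 to 0.663). Ncmap changed by -2.75 ± 0.49 at day 4, while the neuregulin receptor Erbb3 rose by 2.37 ± 0.18. Of 8 mast cell and basophil markers there were 3 higher and 3 lower; 3 higher and 5 lower; 3 higher and 1 lower; 6 higher and 0 lower (medians -0.87, -0.99, 0.23 and 1.32, or 1.13 at bounds for day 15; the first 2 positive with library size alone; adjusted p of 0.167 to 0.838). At day 7 the receptor Kit rose by 2.93 ± 0.30, Hdc, which makes histamine, rose by 1.26 ± 0.42 with 5 of 6 libraries in that direction, and Tpsb2, a tryptase with close relatives, changed by -1.67 ± 0.48; Hdc lost its call without female day 7 replicate 3 (0.83). Adjusted over the list alone, the called members were 10, 5, 8 and 7 Schwann and 8, 8, 3 and 6 mast cell genes.

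Of 16 angiogenic factors there were 9 higher and 6 lower; 5 higher and 4 lower; 7 higher and 3 lower; 9 higher and 2 lower (medians 0.72, 0.02, 0.24 and 0.81, with camera pointing down at day 7; adjusted p of 0.312 to 0.923). At day 4 Angptl4 and Apln rose by 3.98 ± 0.38 and 2.95 ± 0.29, and Vegfb changed by -2.73 ± 0.26. Of 22 Wnt signalling genes there were 9 higher and 6 lower; 12 higher and 4 lower; 13 higher and 4 lower; 11 higher and 3 lower (medians 0.61, 0.67, 1.18 and 0.50; adjusted p of 0.162 to 0.467); at day 11 the secreted Wnt antagonist Sfrp2 rose by 8.03 ± 0.73, Ccn4 by 5.85 ± 0.51, and the ligand Wnt4 changed by -3.85 ± 0.52. Of 4 keratinocyte genes there were 1 higher and 1 lower; 2 higher and 0 lower; 2 higher and 0 lower; 2 higher and 0 lower (medians -0.15, 0.47, 0.55 and 0.86, positive at day 4 with library size alone; adjusted p of 0.331 to 0.633), with Sbsn at 0.80 ± 0.20 and Krt10 at -1.03 ± 0.19 at day 4, the latter positive with library size alone. Of 5 erythroid genes there were 0 higher and 0 lower; 0 higher and 1 lower; 0 higher and 1 lower; 3 higher and 0 lower (medians 0.83, -0.49, -0.24 and 1.58, with camera pointing down at day 4 and days 7 and 11 flipping with library size alone; adjusted p of 0.368 to 0.825). Of 5 Y-linked and X-inactivation genes there were 0 higher and 0 lower; 0 higher and 0 lower; 4 higher and 0 lower; 1 higher and 0 lower (medians -0.35, 1.02, 5.69 and -0.02, with camera pointing down at day 7 and days 4 and 15 flipping with library size alone; adjusted p of 0.751 to 0.853). Adjusted over the list alone, the called members were 16, 9, 10 and 11 angiogenic, 15, 16, 17 and 14 Wnt, 2, 2, 2 and 2 keratinocyte, 0, 1, 1 and 1 erythroid and 0, 0, 4 and 0 sex-linked genes.

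The library labelled female day 11 replicate 3 may be a wrongly labelled male sample or a male sample from elsewhere. A swap within the series is argued against, as the highest Xist among libraries labelled male was 3.49 CPM, and a mixture of male and female RNA is argued against by Xist at 0.0246% of the mean of the other female libraries. A test of whether its 5 sex-linked genes lay within the range of the libraries labelled male gave 2 of 5, since Uty, Eif2s3y and Kdm5d lay above it (28.0, 147 and 20.96 CPM against highest male values of 22.4, 121 and 17.1), which is not toward the female level. A distance test, added after that result, found 5 of 5 closer to the male mean. No biological explanation was tested.

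The immediate early genes at day 15 might reflect the tissue or its handling. Lower depth of the day 15 libraries is argued against, since 9 members were still called against day 11 with every library thinned to the smallest total. More RNA from a cell type whose markers rose was tested first against the upper quartile of the erythroid list (1.61, median 1.47; 5 genes, none of them a haemoglobin), which 5 members exceeded with their whole 95% interval, arguing against it. A test added after that result, against the adipocyte upper quartile (2.46), left 2 members so far above, Fos and Fosb, so for the others it cannot be told apart. All 6 day 15 libraries (males 6.19 to 6.38, females 6.96 to 7.88) lay above all others (3.34 to 5.34), which restates the pattern. No label names a batch, so handling or batch cannot be told apart from a muscle response.

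Other splits of the same libraries were counted for the remaining results, with labels reassigned within each sex. For females against males in uninjured muscle they were reassigned between the sexes. For injured against uninjured muscle only the real of 25 splits (1 of 25, the smallest share possible) reached its count, which argues against a chance split. The counts were 12526 at day 4 (highest other 5775), 12259 at day 7 (10626), 12406 at day 11 (9406) and 11823 at day 15 (9435). The same held for day 7 against day 4 (6034, highest other 1306) and day 15 against day 4 (8934 and 4688). For day 11 against day 7, 6 of 25 splits reached the real 10, and the highest other called 2867, which points to a structure of the samples, which was not identified; for day 15 against day 11, 2 of 25 reached 727 (highest other 743). Chance is not excluded for these. Females against males (110, highest other 4) and the tests within a sex have 10 splits, too few for a share under 0.05. Within males the real counts were 9858, 8804, 8755 and 8167 and the highest other 0 at each day, and within females 11096, 11020, 11235 and 10493 against 0, 0, 227 and 1.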
